A study of Mus musculus with 12 samples.

How the data were processed

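Total RNA of cardiac ventricles from C57BL/6 mice aged 8 weeks was sequenced in 12 libraries, 3 in each of 4 groups. The groups cross a genotype (wild-type, or transgenic for a dead Cas9 fused to the VPR activation domains under the heart muscle promoter of Myh6) with an injection (saline, or an AAV9 vector called TRISPR that the labels name together with Mef2d). They are called WT_saline, WT_AAV, TG_saline and TG_AAV below. Groups and replicate numbers were taken from the sample titles. The labels do not say that the samples of a group are separate animals, so the p-values measure the spread between these samples, which may be technical in part. Each group held libraries with high Xist and libraries with high Ddx3y, and so came from at least 2 animals.

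The authors deposited a table of normalized counts per gene symbol, a signal unit made of gene read counts divided by a size factor per library. The tools listed per the submitters' processing notes are Bowtie2 2.0 and DESeq2, with the genome build mm9, and the role of each tool, the gene annotation, the counter, the strand setting and the filters are not given in the sources used here. Within each column the positive values were whole multiples of the same step, so that whole reads were recovered by dividing by that step. The share of positive values within 0.01 of a whole read was 100% in each of the 12 libraries. The recovered totals ran from 10233281 to 14911986 reads per library. The table held 24390 gene symbols, of which 5583 were at 0 in every library. A spreadsheet had turned 27 symbols into dates. These were kept as anonymous genes, 21 of them were tested, and none is named. Because the table gives a single value per gene symbol, isoforms were not analysed here. The authors' size factors assume that most genes do not differ between libraries, so a change shared by most genes would not be visible.

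The values were tested as log2(normalized count + 1) with limma (version 3.58.1, R 4.3.3), with a trend of the variance on the mean and a mean for each of the 4 groups in a single fit of all 12 libraries. A fold change is on this scale, which understates the change of genes with few reads. Genes with a mean normalized count of 10 or more over the 12 libraries were tested, which left 13030. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. Comparisons were TG_AAV against the mean of the 3 control groups, TG_AAV against each control group, the vector alone (WT_AAV against WT_saline), the transgene alone (TG_saline against WT_saline) and the interaction, which is the vector effect in transgenic hearts minus that in wild-type hearts. Mef2d was also tested on its own with an exact two-sided permutation test of the group means.

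Gene lists numbered 38, of which 36 had at least 3 tested members. They were tested with limma's camera at a preset correlation of 0.01, two-sided, with adjustment over the 36 lists within a comparison. The test was repeated with a correlation estimated for each list and with fry, which asks whether the members of a list move one way on balance without comparing them with other genes. Agreement between a pair of effects that share no library was measured as Pearson's r and Spearman's rho across genes, against all 400 regroupings of the libraries, with the labels exchanged within each of the 2 differences.

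Genes were named by a fixed rule. For TG_AAV against the controls these are up to 12 genes that rose and 12 that fell, with the largest log2 change among those past the threshold whose 3 TG_AAV values all lie outside the range of the 9 control values. For the other comparisons they are up to 6 in each direction whose groups do not overlap. Where no gene passed, the 3 of smallest p in each direction were named. Members of gene lists are named in order of their p. Some genes that these rules pick are not reported here. The groups, the comparisons, the tests, the gene lists, the naming rule and most alternatives were fixed before the data were examined.

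Alternatives were other pseudocounts, filters and scalings, a robust variance estimate, a replicate term, a fit of only the groups compared, omission of each library in turn, and count models on the recovered reads with edgeR 4.0.16 and DESeq2 1.42.0. After the data had been seen, 8 more were added, namely terms for Xist, for libraries with Myh2 reads, for the atrial transcript Myl7 and for a split of the wild-type libraries, omission of 3 libraries rich in atrial transcripts or of 3 wild-type libraries that stand apart, a correction of each library for GC content and transcript length, and thinning of the reads to the smallest library. The reference used for gene names, lengths, GC content, neighbours and shared sequence was GENCODE M21 on GRCm38, another build than that of the authors, and no coordinates are given for that reason. Transcript length and GC content were found for 12924 of the 13030 tested genes. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

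The comparison of TG_AAV with the controls was tested on simulated counts for the 13030 genes, with 50 genes changed at each of several sizes. The test recovered 52% of genes raised 1.5-fold, 90% of those raised 2-fold, 100% of those raised 4-fold and 88% of those lowered to 0.5 of their level, with 11 false calls. For the interaction the shares were 4%, 42%, 98% and 32%, with 6 false calls, so that most of the simulated interactions of 1.5-fold, 2-fold and 0.5 were missed. A simulation of WT_AAV against WT_saline with no changed gene gave 0 false calls. The simulated counts were negative binomial with the real gene means and library sizes, drawn separately per gene, with a spread set from the mean. They held none of the structure within groups described below, so these shares need not hold for the real libraries. A level of 3 reads, taken as the floor in a library, corresponded to 2.19 to 3.45 normalized counts. Intervals of read ratios are exact 95% binomial intervals, and they and the floors cover counting error only.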

Results

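The series measured gene expression in mouse cardiac ventricles in which the endogenous Mef2d gene was to be activated after birth. The activator, a nuclease-dead Cas9 fused to the transcription activating VPR domains, is made in heart muscle cells from the Myh6 promoter. The AAV9 vector, which the labels name with Mef2d, was taken to carry the guide RNAs that direct such an activator to a promoter. There were 3 libraries in each of the 4 groups WT_saline, WT_AAV, TG_saline and TG_AAV, all from mice aged 8 weeks, and only TG_AAV holds both components. Depth ran from 10233281 to 14911986 reads assigned to genes per library, and the giant sarcomere gene Ttn took 9.95% to 11.8% of them. Libraries of the same group differed by more than counting noise, with a chi-square per degree of freedom of 5.18 to 27.1, so no library was a copy of another of its group.

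Mef2d, the transcription factor named with the vector, was higher in the hearts with both components than in any control library. Its normalized count was 1989, 2231 and 1897 in the 3 TG_AAV libraries. It was 999, 877 and 1178 in WT_saline, 973, 1131 and 1102 in WT_AAV, and 833, 844 and 839 in TG_saline. The TG_AAV mean of 2039 ± 173 (SD, n = 3) was 2.09 times the control mean of 975 ± 136 (SD, n = 9), with an exact two-sided permutation p of 0.00455, the smallest that 3 against 9 libraries can give. On the log2 scale Mef2d rose by 1.07 (SE 0.09, limma adjusted p = 5.01e-06). The ratio was 2.43 against TG_saline, 1.91 against WT_AAV and 2.00 against WT_saline, and for these the exact permutation p was 0.1 each, the smallest that 3 against 3 can give. Without the activator the vector left Mef2d at 1.05 times its WT_saline level (exact permutation p = 0.7), by the labels as given. The activator without guides left Mef2d at 0.824 times, with all 3 TG_saline values below those of WT_saline (exact permutation p = 0.1, again the smallest possible, and limma adjusted p = 0.342). The interaction of transgene and vector on Mef2d was 1.20 on the log2 scale (SE 0.15, limma adjusted p = 0.00162).

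Among the other members of the MEF2 family, Mef2a fell by 0.32 on the log2 scale in TG_AAV (SE 0.10, limma adjusted p = 0.0356), a call that was lost without any of the 3 TG_AAV libraries, without WT_saline 1, TG_saline 1 or TG_saline 2, and without the 3 libraries richest in atrial transcripts, with adjusted p up to 0.138 and a log2 change that stayed between -0.346 and -0.298. Mef2a also differed among the wild-type controls. It stood at 3343, 3253 and 3051 in WT_saline 3, WT_AAV 2 and WT_AAV 3, the 3 wild-type libraries that stand apart. In WT_saline 1, WT_saline 2 and WT_AAV 1 it stood at 4059, 4384 and 4220, and its TG_AAV mean was 2928. Across that split of the wild-type libraries, 1 of the 3 tested family members was called higher, Mef2d, and 2 lower, Mef2a and Mef2c. Mef2d stood at 1178, 1131 and 1102 in WT_saline 3, WT_AAV 2 and WT_AAV 3. In WT_saline 1, WT_saline 2 and WT_AAV 1 it stood at 999, 877 and 973. In TG_AAV against the controls Mef2c had a log2 change of -0.10 (limma adjusted p = 0.460). Mef2b lay below the filter, with 0 reads in the TG_AAV libraries. The list of genes next to Mef2d had 7 tested members, of which Apoa1bp (0.29) and Iqgap3 (0.76) rose, Nes (-0.26) fell and Gpatch4, Tsacc, Cct3 and Smg5 did not pass. Adjusted over the list alone, 3 rose and 1 fell. As a list these neighbours did not differ from other genes (limma camera adjusted p = 0.287).

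**Figure D1:**
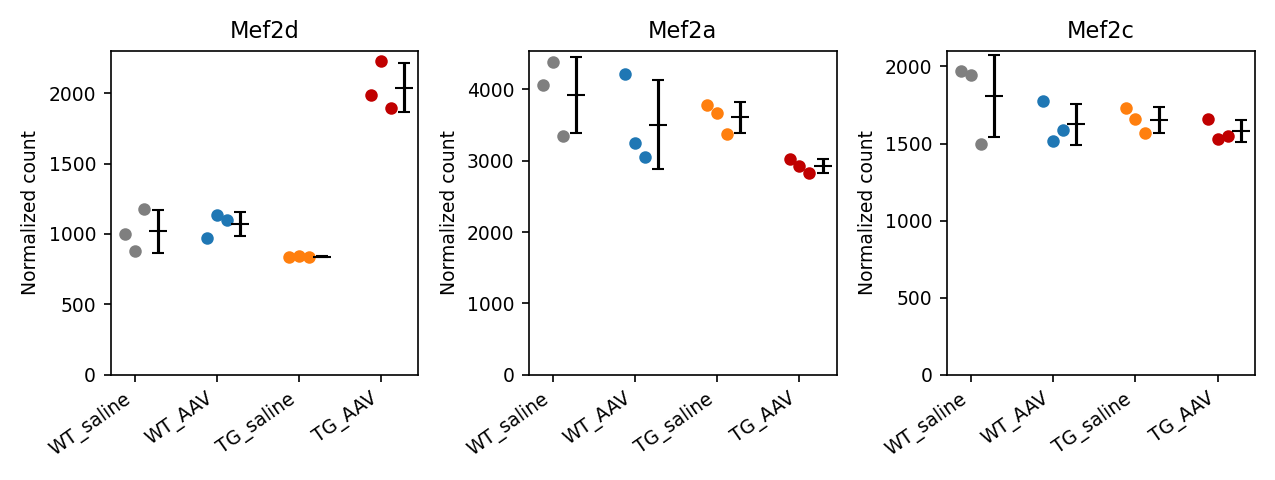
Normalized counts of Mef2d, Mef2a and Mef2c by group, with a point per library and, beside the points, the mean of 3 libraries with its SD. Mef2d lies at 1897 to 2231 in TG_AAV and at 833 to 1178 in the 9 control libraries.

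TG_AAV was compared with the mean of the 3 control groups to ask what the full system changed in these hearts. Several genes that were nearly silent in the controls rose. Ryr1, the calcium release channel of skeletal muscle, reached 1677 ± 286 normalized counts (SD, n = 3) against 13.8 ± 7.55 in the controls (n = 9). Kndc1, B3gat1 (an enzyme of the HNK glycan epitope), Atp1b4 and Clstn3 (a synaptic adhesion protein) rose from between 1 and 16 reads over all 9 control libraries to between 270 and 572 reads over the 3 TG_AAV libraries. Cenpf, a centromere protein, fell from 1079 ± 397 to 123 ± 55.2, and Efnb3, an ephrin ligand, from 1083 ± 200 to 166 ± 38.6. Of 17 stress and fetal genes 11 rose, and of 35 genes of the TCA cycle and respiratory chain 26 fell.

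In all, 1568 genes rose and 1262 fell, 2830 of the 13030 tested (limma, two-sided, adjusted p under 0.05). The edgeR test on the recovered reads called 2928 genes and DESeq2 3115. Of the called genes, 255 rose and 137 fell by more than 2-fold, and 52 rose and 22 fell by more than 4-fold. In 2276 genes, 17.5%, the 3 TG_AAV values lay outside the range of the 9 control values, against 0.909% by chance, and 1987 of these were called. The count was 1677 without TG_AAV 1, 1715 without TG_AAV 2 and 1614 without TG_AAV 3, and 1708 without the 3 libraries richest in atrial transcripts.

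The 12 genes that rose most, on the log2 scale with the pseudocount, were Kndc1 (7.03, SE 0.48), Ryr1 (6.99, SE 0.33), B3gat1 (6.09), Atp1b4 (5.85), Clstn3 (5.62), Col22a1 (4.68), Ccno (4.55), Edn3 (4.42), Pacsin1 (4.08), Pdzd4 (4.0), Tigd4 (3.88) and Itpka (3.87). Their limma adjusted p ran from 9.58e-10 for Pdzd4 to 0.000553 for Pacsin1. Because the controls held few reads, the size of the largest changes is loosely bounded. The ratio of reads was 448 (95% interval 152 to 2178) for Kndc1 with 3 control reads and 634 (113 to 25140) for B3gat1 with 1. For Ryr1, with 121 control reads, it was 119 (99.7 to 144). Col22a1, a collagen of muscle junctions, reached 308 ± 5.43 against 11.9 ± 4.63, and Pdzd4 699 ± 11.1 against 43.1 ± 6.44. Edn3 encodes an endothelin peptide, Pacsin1 a neuronal endocytosis protein and Itpka an inositol trisphosphate kinase.

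Among the 12 genes that fell most were Cenpf (-3.14, SE 0.24), Scn10a (-2.92, SE 0.56), Aqp4 (-2.82), Cdh20 (-2.78), Oprd1 (-2.71), Lrrc4b (-2.70), Efnb3 (-2.70), Kcnv2 (-2.63), Abca4 (-2.58), Cubn (-2.47) and Kcnq5 (-2.41). Their limma adjusted p ran from 7.11e-08 for Efnb3 to 0.00313 for Kcnq5, and the call of Kcnq5 was lost without the 3 libraries richest in atrial transcripts (-1.87, adjusted p = 0.0628). Scn10a is a voltage-gated sodium channel, Kcnv2 and Kcnq5 are potassium channel subunits, Aqp4 is a water channel, Oprd1 an opioid receptor and Cubn an endocytic receptor. Several of these genes were already lower in TG_saline. The means in WT_saline, WT_AAV, TG_saline and TG_AAV were 335, 304, 92.5 and 32.5 for Kcnv2 and 265, 240, 104 and 31.0 for Aqp4. Cenpf had 1478, 1080, 678 and 123, while Abca4, at 134, 95.9, 146 and 19.3, was not lower in TG_saline. The TG_AAV means of Scn10a (3.85), Cdh20 (3.43), Oprd1 (1.86) and Kcnq5 (2.30) lay near the floor of 3 reads. The size of their fall is loosely bounded.

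**Figure D2:**
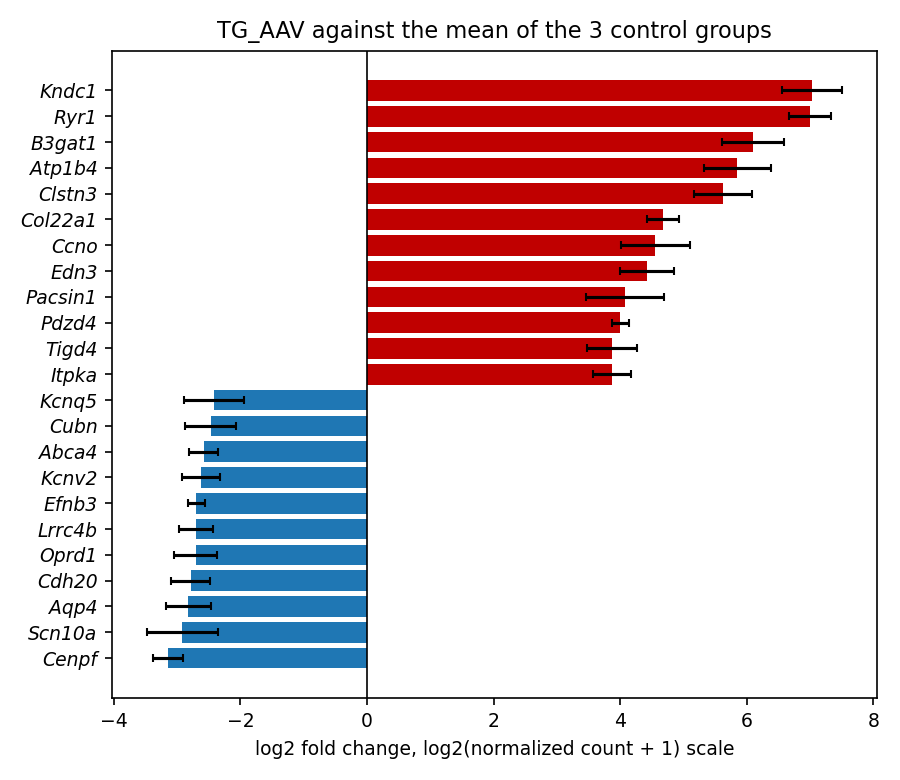
Log2 change of the 12 genes that rose most and 11 of those that fell most in TG_AAV against the mean of the 3 control groups, with bars of 1 SE from the limma fit. The changes run from -3.14 for Cenpf to 7.03 for Kndc1.

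Among the stress and fetal genes, which include markers of strained heart muscle, 11 of 17 rose and 1 fell, and 12 rose and 1 fell adjusted over the list alone. Nmrk2 (2.25), Tnfrsf12a (1.87) and Rcan1 (1.35), an inhibitor of calcineurin, rose, and Fhl1 (-0.97) fell. Nppb, the brain natriuretic peptide, stood at 1859 ± 618 against 433 ± 342 (log2 2.32), and skeletal alpha actin Acta1 at 6092 ± 1930 against 1870 ± 975 (log2 1.86). Nppa had a log2 value of 0.80 and did not pass (adjusted p = 0.0949). The list was higher than other genes (limma camera adjusted p = 1.38e-05; adjusted p = 0.132 with an estimated correlation). Its members Myl7, Myl4 and Nppa are also atrial markers, and Myl7 was over 1000 normalized counts in WT_AAV 1, WT_AAV 3 and TG_AAV 1.

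Of 35 genes of the TCA cycle and respiratory chain, 26 fell and 0 rose (30 and 0 adjusted over the list alone), among them Cox7a1 (-0.69), Ogdh (-0.51), Idh3b (-0.51) and Sdha (-0.51), with a limma camera adjusted p of 4.51e-14 (adjusted p = 0.756 with an estimated correlation). Of 26 genes of fatty acid oxidation, 13 fell and 0 rose (17 and 0 adjusted over the list alone), with lipoprotein lipase Lpl (-0.75), Acaa2 (-0.66), Acot2 (-0.65) and Plin5 (-0.63) in front (limma camera adjusted p = 3.99e-06; adjusted p = 0.756 with an estimated correlation). Of 20 glycolysis genes, 8 fell and 1 rose, as many adjusted over the list alone, with Pfkfb1 (-1.65), Hk2 (-0.58), Ldhb (-0.54) and the glucose transporter Slc2a4 (-0.39) lower (limma camera adjusted p = 0.0293; adjusted p = 0.756 with an estimated correlation). That list was not called with quantile normalization (adjusted p = 0.329) or without TG_saline 2 (adjusted p = 0.0576), and its adjusted p ran from 0.0106 to 0.756 over the alternatives.

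Of 19 cardiac ion channel genes, 8 fell and 2 rose (9 and 2 adjusted over the list alone). Kcnip2, a subunit of the transient outward potassium channel, went from 2149 ± 382 to 783 ± 57.8 (log2 -1.44), and Kcnh2 (-0.95) and Abcc9 (-0.71) were lower as well, with a limma camera adjusted p of 0.000429 (adjusted p = 0.345 with an estimated correlation). Of 20 calcium handling genes, 8 fell and 1 rose, as many adjusted over the list alone, including phospholamban Pln (-0.99), Camk2a (-0.83), Hrc (-0.81) and the cardiac ryanodine receptor Ryr2 (-0.76), with a limma camera adjusted p of 0.0195 (adjusted p = 0.756 with an estimated correlation). The calcium handling list was not called with quantile normalization (adjusted p = 0.461), and its adjusted p ran from 0.00160 to 0.756 over the alternatives.

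Interferon response genes rose in 8 of 29 members and fell in 0 (16 and 0 adjusted over the list alone). Ifit1 (1.14), Irf7 (0.91), Lgals3bp (0.84) and Ifit2 (0.80) led, with a limma camera adjusted p of 1.38e-05 (adjusted p = 0.756 with an estimated correlation). Extracellular matrix and fibrosis genes rose in 11 of 37 members and fell in 2 (12 and 2 adjusted over the list alone), with Ltbp2 (1.81), Col8a1 (1.24), Tgfb3 (0.73) and Timp2 (0.56) higher. The limma camera adjusted p of that list was 0.00534 (adjusted p = 0.756 with an estimated correlation), and 0.0665 without TG_AAV 3. With fry the adjusted p was 0.0814 for the interferon list and 0.0580 for the matrix list. Of 13 fibroblast markers 7 rose and 0 fell, as many adjusted over the list alone, including Mfap5 (0.92), Dcn (0.53), Pdgfra (0.50) and Serping1 (0.40), with a limma camera adjusted p of 0.00342 (adjusted p = 0.756 with an estimated correlation).

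Of 19 circadian clock genes, 9 fell and 3 rose, as many adjusted over the list alone. The output regulator Dbp went from 1804 ± 397 to 736 ± 170 (log2 -1.28), and Ciart (-2.10), Per3 (-0.70) and Hlf (-0.58) fell too (limma camera adjusted p = 0.00602; adjusted p = 0.345 with an estimated correlation).

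**Figure D3:**
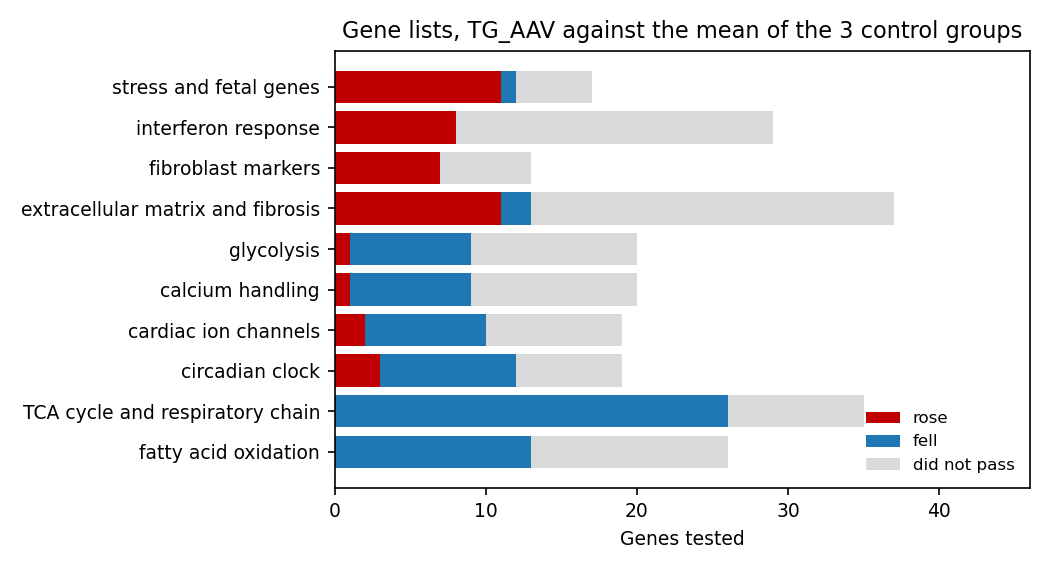
Number of tested members that rose, fell or did not pass in TG_AAV against the mean of the 3 control groups, for the 10 lists called by camera at the preset correlation. The TCA cycle and respiratory chain list has 26 of 35 members lower and the stress and fetal list 11 of 17 higher.

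Of the 36 lists tested, 10 were called at the preset correlation and 0 with an estimated correlation. Fry, which does not compare a list with other genes, called those of the 10 other than the interferon and matrix lists. It also called the unfolded protein response (fry adjusted p = 0.0298), cytokines and chemokines (0.0133) and the MEF2 family (0.00530), which holds Mef2d itself. The MEF2 target genes were called by neither test (limma camera adjusted p = 0.870, fry adjusted p = 0.888). Of 22 members 4 rose and 2 fell, both over all genes and adjusted over the list alone, with muscle creatine kinase Ckm (-0.99) lower and Acta1 (1.86), Xirp2 (0.82) and Xirp1 (0.73) higher. Their median was -0.05 and their mean 0.09. Of 22 sarcomere genes 1 rose and 4 fell (1 and 5 adjusted over the list alone), namely Tpm1 (-0.55), Tnni3 (-0.43), Tnnt2 (-0.40) and Myoz2 (-0.37) lower. Of 20 genes of the unfolded protein response 5 rose and 1 fell, with Sdf2l1 (0.75) and Dnajc3 (0.43) higher. Of 15 metabolic regulators 0 rose and 3 fell, led by Sirt3 (-0.51). Of 19 cardiac transcription factors 2 rose and 3 fell, with Hand2 (-0.94) and Hopx (-0.53) lower and Gata4 (0.34) higher. Of 21 immediate early genes 1 rose (Cyr61, 0.77) and 3 fell, led by Ier2 (-0.87). Of 18 genes of the p53 response 3 rose and 1 fell, with Phlda3 at 0.87. Of 17 heat shock genes 2 rose, Bag3 (0.46) and Hsp90aa1 (0.69), and 0 fell. Of 20 apoptosis genes 4 rose and 3 fell, with Bak1 at 0.57. Of 25 cell cycle genes only Ccnd2 (0.65) rose and only Cenpf fell.

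Markers of other cell types were tested in the same way. Of 16 endothelial markers 0 rose and 3 fell, Cdh5 (-0.43), Esam (-0.32) and Vwf (-0.49), with a limma camera adjusted p of 0.0836. Of 12 mural cell markers 1 fell (Abcc9), of 9 atrial markers 2 fell (Clu, -0.60, and Kcnj3, -0.98), of 7 epicardial markers 1 fell (Wt1, -0.52), and 0 rose in these 3 lists. Of 6 adipocyte markers Thrsp (1.42) rose and Cidea (-0.59) fell, and of 8 Schwann and neuronal markers Uchl1 (1.52) rose and Dbh (-2.13), an enzyme of noradrenaline synthesis, fell. Of 5 skeletal muscle markers Cacna1s (0.51) rose and 0 fell. Of 17 antigen presentation genes 0 rose and 3 fell, H2-Ab1 (-0.82), H2-Eb1 (-0.66) and Cd74 (-0.59), and of 12 cytokine and chemokine genes 0 rose and 4 fell, led by Cxcl12 (-0.53). By limma 0 members passed among 18 macrophage and monocyte markers, 3 erythrocyte markers, 28 ribosomal protein genes, 9 core histone genes and 5 sex-linked genes. Lymphocyte and neutrophil markers had 2 tested members and mitochondrially encoded genes 0, too few for a list test. Myh7, the slow myosin heavy chain, shares sequence with the far more abundant Myh6 and is uncertain in this table (log2 0.74, limma adjusted p = 0.574).

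Against TG_saline, which differs by the whole vector in hearts that already hold the activator, 481 genes rose and 313 fell (limma, 794 of 13030). Kndc1 (6.82), Ryr1 (6.43), Atp1b4 (6.39), B3gat1 (6.22), Clstn3 (5.71) and Col22a1 (5.23) rose most, and Scn10a (-2.93), Abca4 (-2.86), Cdh20 (-2.78), Lrrc4b (-2.75) and Cenpf (-2.54) were among those that fell most. Of 17 stress and fetal genes 9 rose and 1 fell (11 and 1 adjusted over the list alone), with Tnfrsf12a (1.36) and Rcan1 (1.17) higher. Of 35 TCA cycle and respiratory chain genes 13 fell and 0 rose (25 and 0 adjusted over the list alone), led by Cox7a1 (-0.64) and Cs (-0.55). Of 13 fibroblast markers 4 rose and 0 fell (7 and 0 adjusted over the list alone), and of 37 matrix genes 7 rose and 0 fell (10 and 0 adjusted over the list alone), with Cilp (2.08) and Col8a1 (1.21) higher. The adjusted p of limma's camera was 1.16e-05, 3.50e-15, 0.000309 and 0.00808 for these 4 lists (adjusted p = 0.124, 0.694, 0.694 and 0.782 with an estimated correlation). The interferon, fatty acid oxidation, glycolysis and calcium handling lists were called as well. In them 1, 0, 0 and 0 members rose and 0, 1, 0 and 5 fell. The cardiac ion channel and circadian clock lists were not called here (limma camera adjusted p = 0.0573 each). In these 4 and 4 members fell and 2 and 1 rose. In all 8 lists were called at the preset correlation, 0 with an estimated correlation and 3 with fry. The fry calls were stress and fetal genes (fry adjusted p = 0.00311), the MEF2 family (0.00459) and cytokines and chemokines (0.0416). Of these only the stress and fetal list is among the 8. In the MEF2 family Mef2d itself (1.28) was the only 1 of 3 tested members to pass over all genes, and the median of the list was -0.06. The TCA cycle and fibroblast lists had a fry adjusted p of 0.0828 each. The camera list count was 5 without TG_saline 2 and 13 without the 3 libraries richest in atrial transcripts.

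The edgeR test called 871 genes against TG_saline and DESeq2 1182, and 4401 genes (33.8%) had groups that did not overlap, against 10% by chance. The limma count was between 399 and 500 without any of the 3 TG_AAV or the 3 TG_saline libraries, 524 without the 3 libraries richest in atrial transcripts, 1708 when only these 2 groups were fitted and 1345 with a term for a split of the wild-type libraries, which enter only the shared estimate of the spread.

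Against WT_AAV, which differs by the transgene in hearts that got the vector, 1385 genes rose and 1065 fell (limma, 2450 of 13030). The genes that rose most were Ryr1 (7.64), Kndc1 (6.96), B3gat1 (6.22), Clstn3 (5.62), Atp1b4 (5.13) and the cyclin Ccno (5.12). Those that fell most were Kcnv2 (-3.21), Cenpf (-3.21), Aqp4 (-3.20), Oprd1 (-3.02), Cubn (-2.97) and Efnb3 (-2.86). The TCA cycle and respiratory chain list had 19 of 35 members lower and 0 higher (24 and 0 adjusted over the list alone), the fatty acid oxidation list 12 of 26 lower and 0 higher (15 and 0), the stress and fetal list 11 of 17 higher and 1 lower (as many adjusted over the list alone), and the ion channel list 7 of 19 lower and 2 higher (10 and 2). Their limma camera adjusted p was 2.20e-11, 4.86e-06, 0.000275 and 0.000351 (adjusted p = 0.693, 0.693, 0.295 and 0.305 with an estimated correlation). In all 11 lists were called, and 0 with an estimated correlation. The 11 included immediate early genes, with 3 of 21 members lower (limma camera adjusted p = 0.00657; adjusted p = 0.693 with an estimated correlation), and endothelial markers, with 2 of 16 lower (0.0249; 0.693 with an estimated correlation). The edgeR test called 2533 genes and DESeq2 2790, and 4953 genes (38.0%) did not overlap, against 10% by chance. The limma count was 1535, 1600 and 1449 without TG_AAV 1, 2 and 3, and 713 without WT_AAV 1, WT_AAV 3 and TG_AAV 1, the 3 libraries richest in atrial transcripts, which leaves a lone WT_AAV library that is assumed to vary like the rest.

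Against WT_saline, which sets the full system beside plain hearts, 1340 genes rose and 1092 fell (limma, 2432 of 13030). Kndc1 (7.31), Ryr1 (6.91), Atp1b4 (6.03), B3gat1 (5.85), Clstn3 (5.54) and Edn3 (5.25) rose most, and Cenpf (-3.68), Aqp4 (-3.28), Kcnv2 (-3.25), Scn10a (-3.25), Lrrc4b (-3.06) and Cdh20 (-3.01) fell most. The stress and fetal list had 12 of 17 members higher and 1 lower, the ion channel list 10 of 19 lower and 2 higher, both as many adjusted over the list alone, and the TCA cycle and respiratory chain list 22 of 35 lower and 0 higher (29 and 0 adjusted over the list alone). Their limma camera adjusted p was 3.81e-06, 3.00e-05 and 5.69e-13 (adjusted p = 0.0912, 0.224 and 0.771 with an estimated correlation). In all 9 lists were called, 14 with no filter on the genes and 0 with an estimated correlation. The edgeR test called 2491 genes and DESeq2 2704, and 4996 genes (38.3%) did not overlap, against 10% by chance. The limma count was 1549 without TG_AAV 1 and 1494 without TG_AAV 3.

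WT_AAV against WT_saline asks what the vector does where no activator is present. No gene passed, with 0 calls by limma, 0 by edgeR and 11 by DESeq2, and 514 genes at an unadjusted limma p under 0.05. The genes of smallest p were the matrix genes Ltbp2 (103 ± 14.6 against 31.3 ± 15.2, n = 3 each, limma adjusted p = 0.263) and Thbs1 (289 ± 72.6 against 81.3 ± 28.1, limma adjusted p = 0.263), Mrpl48 (log2 0.80, limma adjusted p = 0.322), and on the lower side the mitochondrial carrier Ucp2 (426 ± 36.5 against 886 ± 114, limma adjusted p = 0.242), Hddc3 (-1.40) and Pycard (-0.74). Groups did not overlap in 790 genes, 6.06% against 10% by chance. With no member past the threshold over all genes, 10 lists were still called at the preset correlation, and 0 with an estimated correlation or with fry. Among the 10 were immediate early genes (limma camera adjusted p = 7.01e-07; adjusted p = 0.432 with an estimated correlation), atrial markers (0.000358; 0.432 with an estimated correlation) and adipocyte markers (0.000617; 0.432 with an estimated correlation). The atrial transcript Myl7 stood at 2042 and 1693 in WT_AAV 1 and WT_AAV 3, at 3.04 in WT_AAV 2 and at no more than 8.88 in WT_saline. Leaving out WT_AAV 2 or WT_AAV 3 gave 2 calls, and leaving out TG_AAV 1 or TG_AAV 3 gave 1. Without WT_saline 3, WT_AAV 2 and WT_AAV 3, which stand apart from the other wild-type libraries, there were 45 calls, with a lone WT_AAV library assumed to vary like the rest. The count of 10 lists was 3 without WT_AAV 1, 4 with a term for Myl7, 4 without the 3 libraries richest in atrial transcripts and 16 without the 3 wild-type libraries that stand apart.

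TG_saline against WT_saline asks what the activator does without guides. Rab40b rose from 28.6 ± 2.16 to 97.5 ± 7.88 (SD, n = 3 each; log2 1.73), Alad, an enzyme of haem synthesis, from 558 ± 68.7 to 1083 ± 45.0 (log2 0.96), and the Wnt receptors Fzd9 (1.80) and Fzd3 (1.14), the GABA transaminase Abat (1.25) and the kinase Prkcz (1.37) rose too. Ces1d, a carboxylesterase, fell from 1841 ± 302 to 760 ± 117 (log2 -1.27) and Pfkfb1, a regulator of glycolysis, from 276 ± 65.0 to 94.7 ± 20.5 (log2 -1.53). In all 11 genes rose and 2 fell by limma, against 36 calls by edgeR and 220 by DESeq2, and 1462 genes had an unadjusted limma p under 0.05. Groups did not overlap in 2157 genes, 16.6% against 10% by chance. The cardiac ion channel list was lower, with 0 of 19 members past the threshold over all genes and 6 adjusted over the list alone, including Kcnj2 (-0.73, limma adjusted p = 0.0553) and Kcnip2 (-0.47). Its limma camera adjusted p was 9.59e-07 (adjusted p = 0.178 with an estimated correlation). Fry called 1 list, counted over all 36 lists. Camera called 9 lists in all and 0 with an estimated correlation, and the fry list need not be among the 9. The camera list count was 3 without WT_saline 2, 3 without TG_saline 3, 4 with a term for the Myh2 reads and 5 with a term for Myl7. The count of 13 depended on single libraries. It was 2 without WT_saline 3, 40 without WT_saline 2, 20 without WT_AAV 1, 4 without WT_AAV 2, 34 without WT_AAV 3, 35, 0 and 2 without TG_saline 1, 2 and 3, and 4, 5 and 3 without TG_AAV 1, 2 and 3.

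The interaction asks which vector effects in transgenic hearts differed from those in wild-type hearts. Ryr1 (7.15), B3gat1 (6.58), Kndc1 (6.46), Clstn3 (5.78), Atp1b4 (5.49) and Ccno (5.22) had the largest positive differences, and Efnb3 (-2.50), Abca4 (-2.29), Cenpf (-2.07), Whrn (-1.63) and Adam23 (-1.35) were among the largest negative ones, all on the log2 scale. Of the stress and fetal list, Nmrk2 (3.03) and Rcan1 (1.26) differed upwards and Fhl1 (-0.86) downwards, 2 and 1 of 17 members (7 and 1 adjusted over the list alone; limma camera adjusted p = 0.00450; adjusted p = 0.577 with an estimated correlation). Of the TCA cycle and respiratory chain list 0 of 35 members passed, with a median of -0.33 (limma camera adjusted p = 1.85e-11; adjusted p = 0.577 with an estimated correlation). In all 111 genes passed by limma, 80 upwards and 31 downwards, against 104 by edgeR and 274 by DESeq2, with 1522 at an unadjusted limma p under 0.05, and 9 lists were called, 0 with an estimated correlation and 1 with fry. Among the 9 was the list of atrial markers, with 1 of 9 members lower and a median of -0.92 (limma camera adjusted p = 0.00389; adjusted p = 0.577 with an estimated correlation), which shares Myl7, Myl4 and Nppa with the stress and fetal list. The gene count was 63, 52 and 192 without WT_saline 1, 2 and 3, 70 without WT_AAV 2, 54, 73 and 69 without TG_saline 1, 2 and 3, and 55, 39 and 42 without TG_AAV 1, 2 and 3.

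The effect of the transgene was compared across genes between saline and vector hearts, and the effect of the vector between wild-type and transgenic hearts, each as a pair of differences that share no library. The transgene effects had r = 0.415 and rho = 0.478 over 13030 genes, which are not independent replicates. Among 400 regroupings the permutation p was 0.03 for r (0.06 adjusted over the 2 relations) and 0.01 for rho (0.02 adjusted), the latter the smallest they can give. The vector effects had r = 0.104 (permutation p = 0.48, 0.48 adjusted) and rho = 0.118 (permutation p = 0.12, 0.12 adjusted). The r of the transgene effects did not pass after adjustment, and its unadjusted permutation p was 0.05 or more without WT_saline 2 (r = 0.402), WT_saline 3 (r = 0.302), WT_AAV 2 (r = 0.370) or TG_saline 2 (r = 0.339).

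**Figure D4:**
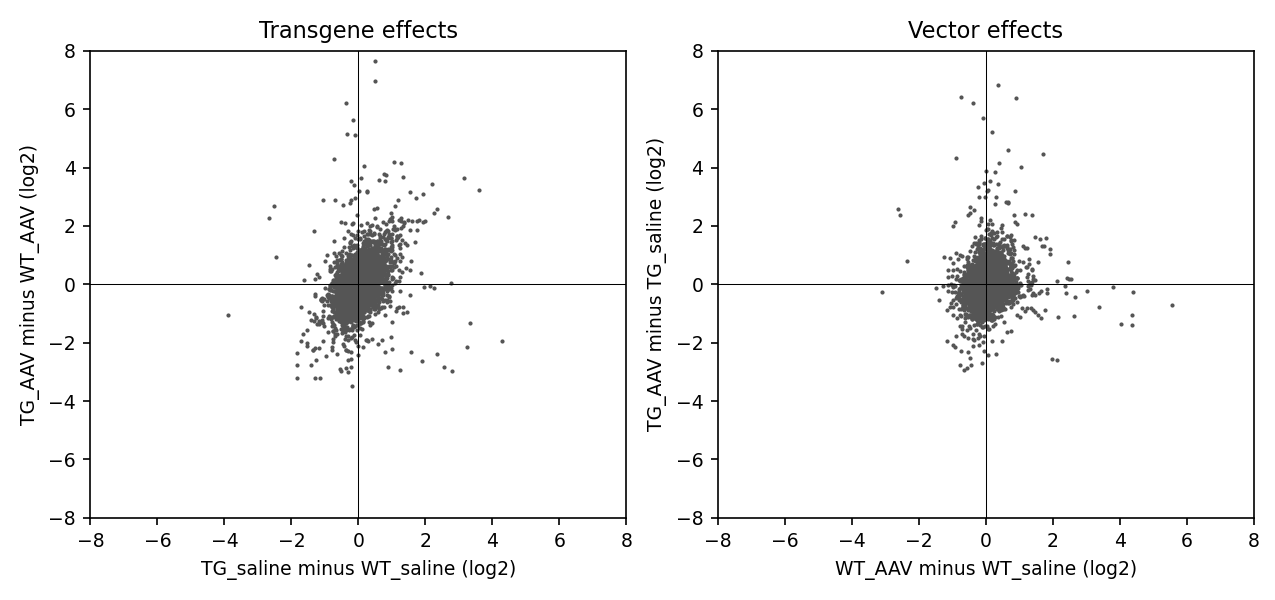
Log2 effects across the 13030 tested genes, with a point per gene. The left panel sets the transgene effect with the vector against that without it (r = 0.415), and the right panel the vector effect with the transgene against that without it (r = 0.104).

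Some transcripts split the libraries in ways the groups do not. In 6 libraries (WT_saline 1 and 3, WT_AAV 1, TG_saline 2, TG_AAV 1 and 2) Myh2 stood at 944 to 1272 normalized counts and Myh7 at 15836 to 23560, and in the other 6 Myh2 stood at 0.796 to 3.04 and Myh7 at 2043 to 4161. Xist was over 1000 normalized counts in 5 libraries and the Y-linked Ddx3y in the other 7, so the libraries hold both sexes, which the labels do not give. High Xist was found in WT_saline 1 and 3, WT_AAV 3, TG_saline 1 and TG_AAV 3. Within the 6 libraries with Myh2 reads Mef2d was higher in TG_AAV by 1.09 on the log2 scale (2 libraries against 4), and in the other 6 by 1.00 (1 against 5).

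**Figure D5:**
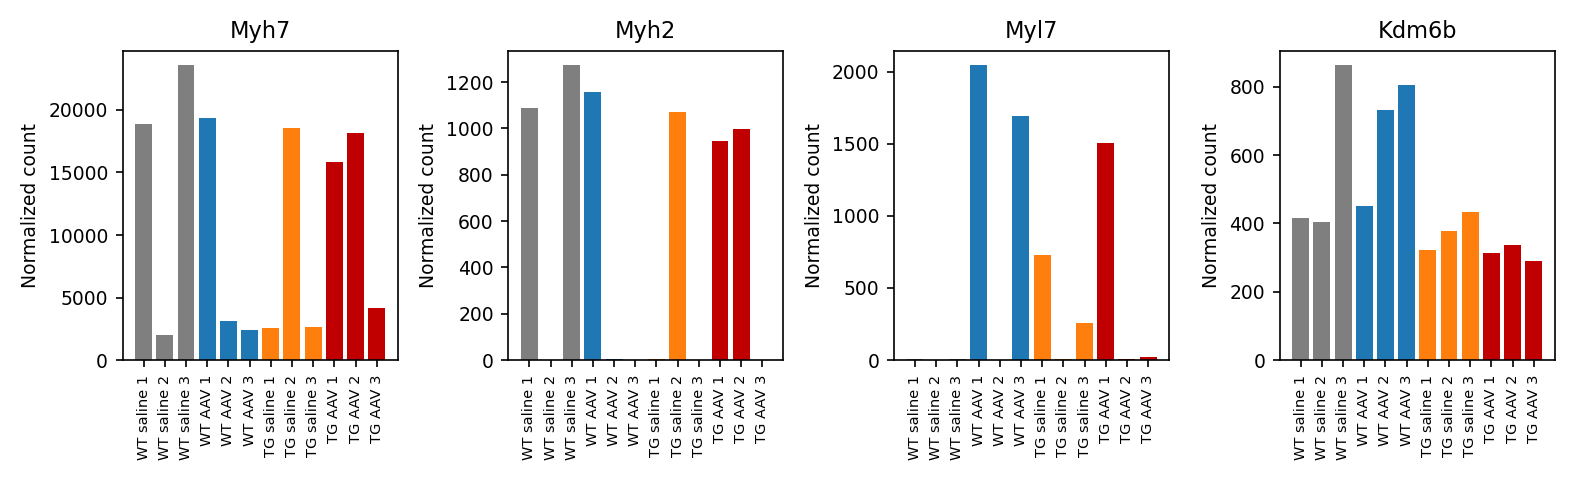
Normalized counts of Myh7, Myh2, Myl7 and Kdm6b, transcripts that vary within groups, with a bar per library from 0 and a colour per group. Myh2 and Myh7 are high in the same 6 libraries, Myl7 is over 1000 in WT_AAV 1, WT_AAV 3 and TG_AAV 1, and Kdm6b is highest in WT_saline 3, WT_AAV 2 and WT_AAV 3 (734 to 863).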

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

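The tests on skeletal muscle tissue and on depth were chosen after the values they measure had been seen, and the test of neighbouring genes was set before its result.

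The vector effect differed between transgenic and wild-type hearts in 111 genes by limma's interaction test, the only results drawn out here for a difference between groups. The named ones were Ryr1 (7.15 on the log2 scale, SE 0.57, adjusted p = 2.84e-05), B3gat1 (6.58, adjusted p = 0.00224), Kndc1 (6.46, adjusted p = 0.00215), Clstn3 (5.78, adjusted p = 0.00388), Atp1b4 (5.49, adjusted p = 0.0152) and Ccno (5.22, adjusted p = 0.0224) upwards. Downwards they were Efnb3 (-2.50, adjusted p = 0.000155), Abca4 (-2.29, adjusted p = 0.0189), Cenpf (-2.07, adjusted p = 0.0385), Whrn (-1.63, adjusted p = 0.0394) and Adam23 (-1.35, adjusted p = 0.0224). Mef2d itself differed by 1.20 (adjusted p = 0.00162). In Adam23 the difference came with WT_AAV values above WT_saline (103 ± 11 against 56.9 ± 14.9, n = 3 each) as well as TG_AAV values below TG_saline (60.1 ± 3.39 against 84.0 ± 3.85). Of 100 splits of the 12 libraries, 5 gave as many calls as the real 111, the real split included, and the highest other gave 1480. The split with 1480 calls set all 6 transgenic libraries against all 6 wild-type libraries. The other splits as large (1023, 271 and 139 calls) kept the 3 TG_AAV libraries together, and the next gave 4 calls. These large counts point to the structure of the samples. Such splits carry differences between the real groups, so their number cannot decide on chance for the 111.

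The 10 genes that rose over 16-fold in TG_AAV were Kndc1, Ryr1, B3gat1, Atp1b4, Clstn3, Col22a1, Ccno, Edn3, Pacsin1 and Pdzd4, of which 8 also passed the interaction test. Skeletal muscle tissue in the TG_AAV samples, which would bring Ryr1, is argued against by the summed counts of 7 fast skeletal muscle genes, with a log2 ratio of -0.18 (SE 0.13) between TG_AAV and the controls. Greater depth is argued against too, since the median log2 change of the 10 genes was 5.08 after thinning all libraries to the smallest and 5.15 before. Activation that spreads to neighbours stays open, with 18.2% of 11 tested nearest neighbours called higher (exact 95% interval 2.28 to 51.8) against 12.0% of other genes (Fisher's exact test, two-sided p = 0.632), too few to decide. For the 52 genes that rose over 4-fold, a set run beside it, the share was 23.2% of 69 neighbours against 11.6% (Fisher's exact p = 0.00702), and binding of the activator near these genes by the guides, or an effect of Mef2d on them, could each account for the rise and were not tested here.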

How the results depend on the processing

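The terms for Xist, Myh2 reads, Myl7 and the wild-type split, the omission of 3 libraries at once, the GC and length correction and the thinning were chosen after the data had been seen. No result changed direction under any alternative run. Mef2d passed under each, with a log2 change of 1.01 to 1.12 when a library was left out. Of 819 values of 26 genes followed under alternatives, 809 kept their side of the threshold, 8 lost it (7 of Mef2a and 1 of Kcnq5) and 2 gained it (Mef2c with the wild-type split term and without those 3 libraries). No scaling moved the median of all genes by over 0.1 on the log2 scale.

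Leaving out each library in turn, the calls ran from 1614 to 3165 for TG_AAV against the controls, 399 to 1058 against TG_saline, 1449 to 2974 against WT_AAV, 1494 to 2814 against WT_saline, 0 to 2 for the vector alone, 0 to 40 for the transgene alone and 39 to 192 for the interaction, with fewer libraries in each fit. Called lists ran from 9 to 13 for TG_AAV against the controls, 5 to 12 against TG_saline, 9 to 13 against WT_AAV, 8 to 11 against WT_saline, 3 to 12 for the vector alone, 3 to 13 for the transgene alone and 6 to 12 for the interaction, the transgene correlation from 0.302 to 0.438 and the vector correlation from 0.0451 to 0.132. With an estimated correlation 0 lists were called.

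For the transgene alone (13 calls) the count was 33 with a pseudocount of 8, 38 with robust variances, 38 with the GC and length correction, 34 with the wild-type split term, 28 without the 3 wild-type libraries that stand apart, 3 with only the groups compared, 2 with the Myh2 term, 3 with the Myl7 term, 4 without the 3 atrial-rich libraries, 36 with edgeR and 220 with DESeq2. For the vector alone (0 calls) it was 1 with no filter, 45 without the 3 wild-type libraries, 4 without the 3 atrial-rich libraries and 11 with DESeq2. The interaction (111 calls) gave 187 with the wild-type split term, 258 without those 3 libraries, 65 with the Myh2 term, 41 with the Myl7 term, 37 without the atrial-rich libraries and 274 with DESeq2. Against TG_saline (794 calls) there were 1345 with the wild-type split term, 1751 without those 3 libraries, 1708 with only the groups compared and 524 without the atrial-rich libraries. Without the latter there were 1708 calls against the controls and 713 against WT_AAV. Each omission of 3 libraries leaves WT_AAV with a lone library, assumed to vary like the rest. The cause of these shifts was not tested.

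The transgene correlation had an unadjusted permutation p of 0.03 (0.06 adjusted), and the unadjusted p was 0.05 or more with the wild-type split term (0.412), the Xist term (0.378), the Myh2 term (0.381) and the Myl7 term (0.400). Whether the replicate numbers pair the samples stays open. The labels do not say so, and 8 of 18 same-number pairs had a correlation over 0.1 (-0.158 to 0.332), not every pair. The 3 pairs of WT_AAV with TG_AAV were all over 0.1 (0.206 to 0.332). In all 8 of 12 libraries matched best a library of their own number in another group, a hint from the data. The mean was 0.0958 for same-number pairs. The mean of -0.0478 for other pairs largely follows from it, since deviations from group means cancel within a group. TG_saline 1 reached 0.345 with TG_AAV 3 and 0.328 with WT_AAV 3, each the only library of its group with high Xist. WT_AAV and TG_AAV also matched in Xist at each number, so pairing was not told apart from sex. With the replicate block the transgene alone gave 32 calls by limma and 32 by edgeR, the transgene correlation of 0.415 had an unadjusted permutation p of 0.09, and no other count moved by over 1.5 times. Depth limits the ratios of genes with few control reads, and 3 libraries per group the interaction.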

Other observations

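The gene families, the clock arms, the wild-type split with its 3 tests, the share of genes moved in TG_saline and the tests of the Myh2 split were chosen after the results had been seen, and the counts over splits of the libraries were set before.

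Of 23 gene families run beyond the fixed lists, 7 were called in TG_AAV against the controls at the preset correlation, and 0 with an estimated correlation. Of 36 NADH dehydrogenase subunits 20 fell and 0 rose (limma camera adjusted p = 1.50e-09; adjusted p = 0.444 with an estimated correlation), of 14 cytochrome c oxidase subunits 9 fell and 0 rose (1.19e-05; 0.444 with an estimated correlation), and of 16 ATP synthase subunits 9 fell and 0 rose (1.60e-05; 0.444 with an estimated correlation). Of 75 mitochondrial ribosomal protein genes 10 fell and 0 rose (0.000738; 0.962 with an estimated correlation). Of 40 mitochondrial carriers 7 fell and 1 rose (0.0255; 0.444 with an estimated correlation). Some members of these families are also in the respiratory chain list. Of 326 zinc finger genes named Zfp, 32 fell and 6 rose (9.90e-05; 0.444 with an estimated correlation), and of 17 aminoacyl-tRNA synthetases 4 rose, Hars, Sars, Wars and Gars, and 0 fell (0.0135; 0.444 with an estimated correlation). Calcium channel genes were not called (0.602; 0.871 with an estimated correlation), with 6 of 14 higher, among them Cacna1a (1.43), and 3 lower, among them Cacna1g (-1.60), which were singled out after their values were seen.

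Of the 2830 genes called in TG_AAV against the controls, 82.0% had a difference of the same sign in TG_saline against WT_saline, where only 13 genes passed, with a median of 0.14 over the genes that rose and -0.16 over those that fell, against 0.46 and -0.48 in TG_AAV. Each of the 20 assignments of the labels to these 6 libraries has a mirror image with all signs reversed, so their median of 50% was fixed in advance. The real assignment was highest, at 82.0%, and the next reached 73.9%. This is consistent with an activator transgene that shifts these hearts part of the way without guides, as a hypothesis. A difference of the transgenic line, such as its litters, could give the same value and was not tested, and transgenic hearts without the activator, which would decide it, were not analysed here.

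In the clock genes, the 8 output genes Dbp, Tef, Hlf, Per1, Per3, Nr1d1, Nr1d2 and Ciart all fell in TG_AAV (mean -0.91, SE 0.15). Each SE in this paragraph is between libraries, from a fit of the 4 groups to the mean of the genes in each library. GC content and length are argued against, since the mean was -0.90 after correction. Collection at another time of day would move genes of the opposite phase the other way, and Arntl, Clock, Npas2, Nfil3 and Cry1 had a mean of 0.56 (SE 0.20), with 3 of 5 higher. The hour of collection is not in the labels and cannot be told apart from the group, so it may account for the pattern, as may an effect of Mef2d. Arntl was 57.6 and 62.8 in TG_AAV 1 and 2 but 18.3 in TG_AAV 3, inside the control range of 11.1 to 35.5.

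The 6 wild-type libraries hold a structure across their groups. Among the 10 splits of these libraries, the one that sets WT_saline 3, WT_AAV 2 and WT_AAV 3 against WT_saline 1, WT_saline 2 and WT_AAV 1, sets defined here from the data, called 1543 genes by limma (681 higher and 862 lower, mean size 0.44 on the log2 scale), among them Kdm6b (734 to 863 against 405 to 451 normalized counts) and Eng, and 15 of 35 TCA cycle and respiratory chain genes lower. Whether the labels of WT_saline 3 and WT_AAV 1 were exchanged is not decided here. With them exchanged, the vector alone would give these 1543 calls, with Mef2d among the higher ones. These genes differed by -8.83e-05 (SE 0.0272) between TG_AAV and TG_saline. That goes against an exchange only if the vector acts alike in both genotypes. The vector effects in the 2 genotypes, by the labels as given, had r = 0.104 (permutation p = 0.48). A larger share of endothelial cells may account for part of the split. The 15 endothelial markers other than Eng were higher by 0.21 on average, and Eng by 0.66. The SE of that average was 0.06 between libraries, 3 against 3, in sets that were themselves chosen from these data. Of the 15 markers 13 were higher, with 4 called higher and 0 called lower. The endothelial list, Eng included, was higher at the preset correlation (limma camera adjusted p = 0.000606), but not with an estimated correlation (adjusted p = 0.951). GC content or length stays open, with 457 of the 1543 genes still called after correction, 497 in all, and a rho of 0.30 with GC content. Across this split limma camera called the TCA cycle (adjusted p = 1.75e-10), fatty acid oxidation (0.00292) and calcium handling (0.0352) lists lower. It called the interferon list (0.0495) higher. Each had an adjusted p of 0.951 with an estimated correlation. The other lists called in TG_AAV against the controls were not called across it.

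Other splits of the libraries gave fewer calls for most comparisons. For TG_AAV against the controls (2830 calls), 1 of 100 splits gave as many, the real one, and the highest other gave 19, so chance is excluded at that share. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Of these, 1 gave as many calls as the real split, the real one itself, against TG_saline (794, highest other 0), against WT_AAV (2450, highest other 0), against WT_saline (2432, highest other 0) and for the transgene alone (13, highest other 1). For the vector alone (0 calls) 10 of 10 gave as many, the highest other being the 1543 above.

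The 6 libraries with Myh2 reads differed from the other 6 in 4 genes by limma, Rprl3, Myh2, Myh7 and Myh1. Rprl3 stood at 1729 to 2289 against 7.50 to 11.9 normalized counts. Stretches of 36 bases shared with a gene 10 times as abundant were found in 4 of the 4, and also in 2666 of 12919 other tested genes (20.6%). Myh7 shared 1782 of its 6195 stretches with Myh6, Myh1 1561 of 6046 with Myh2, Myh2 7 of 6048 with Myh6 and Rprl3 2 of 255 with Rpph1. The summed counts of 7 fast skeletal muscle genes had a log2 ratio of 0.24 (SE 0.16) between the sets.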
